A study of Xenopus laevis with 16 samples.

How the data were processed

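RNA was sequenced from animal caps, ectodermal explants of Xenopus laevis embryos. Embryos received 20 pg of mRNA at the 2-cell stage. The mRNA encoded Ptf1a or Neurog2, bHLH transcription factors, or a Ptf1a protein with the changes W224A and W242A, called the mutant here. Each protein was fused to the hormone-binding GR domain, which makes its activity depend on dexamethasone. The injected caps were kept in medium with dexamethasone for 6 h or 25 h. Control caps were taken at both times, and the labels do not make plain what these had received. The 16 libraries form 8 groups of 2.

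The authors deposited raw gene counts, 1 file per library, which featureCounts made per the labels. The submitters' processing notes also name CASAVA 1.8, STAR 2.5 and DESeq2 1.8. They state no strandedness and no treatment of reads that map to several places. Xenopus laevis carries L and S copies (homeologs) of many genes, and reads may be shared between them. Each file lists 45038 genes, of which 23555 have an L or S symbol and 21425 only a locus identifier. A unique record of the same name in an annotation of build 9.1 exists for 41310 of them, 22 match several records and 3706 match none. Coordinates come from these records. Total RNA was extracted with Trizol and made into standard Illumina libraries per the labels.

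Total counts per library ranged from 31.4 to 228.3 in units of 1e6, with a median of 63.5. Counts are PCR reads without molecular identifiers, so the 95% exact intervals and the floors cover counting error only. Where a group had 0 counts of a gene, the fold is a lower bound computed against a floor of 3 counts over the 2 libraries of that group. Where it had 1 to 3 counts, the ratio of the pooled counts is given with its exact 95% interval. Fitted fold changes of such genes depend on the prior count of 0.125 and are no bounds. CPM values are scaled by TMM, and are given as mean ± SD of the 2 libraries of a group.

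Differential expression was tested in R 4.3.3 with edgeR 4.0.16. TMM normalization and filterByExpr by group left 30384 genes. A quasi-likelihood model (glmQLFit, robust) with a mean per group was fitted to all 16 libraries, with 8 residual degrees of freedom and a common biological coefficient of variation of 0.378. Each comparison used a quasi-likelihood F-test, and p was adjusted by Benjamini-Hochberg over all genes of that comparison. A gene is called when its adjusted p is under 0.05. Without any change, a share of 0.05 of the 30384 genes would be expected at an unadjusted p under 0.05. Log2 fold changes are given with their SE. Injected caps were compared with the control caps of the same time, with each other within a time, and the control caps of 25 h with those of 6 h. An interaction asked whether the effect of each mRNA against its control differed between the times. The labels do not say that the libraries come from separate batches of embryos, so p measures the spread between these samples only.

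The 26 gene lists, the tests and the rule for naming genes were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 on voom values, two-sided, with a preset correlation between genes of 0.01, and adjusted over the 26 lists of a comparison. The test was repeated with the correlation estimated from each list. Members were counted over all genes tested and adjusted over the list alone. The lists held construct and cofactor genes, pan-neuronal differentiation genes, the neuronal transcription factor cascade, Notch ligands and targets, inhibitory neurotransmitter genes, inhibitory fate factors with the Ptf1a programme, excitatory and glutamatergic genes, and sensory neuron, motor and cholinergic, monoamine and peptide, retina, pancreas and glia genes. Others held neural plate, anterior-posterior patterning, epidermis, multiciliated cell, ionocyte and small secretory cell, cement gland, neural crest, mesoderm and muscle, endoderm, early ectoderm, cell cycle, glucocorticoid response, and p53 and stress genes. Several genes stand in more than 1 list. The L and S copies of a gene are separate members, so the list genes counted below are copies, and the number of different genes is smaller. The preset correlation takes copies as nearly independent, though their fold changes against the control correlated at 0.41 to 0.72 across pairs.

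The rule named ptf1a, neurog2 and rbpj in every comparison with the control. It named the 6 genes with the highest and the 4 with the lowest log2 fold change in those comparisons, and 4 of each in the others. These had to have a symbol, be called, have a mean log2 CPM above 0 and show no overlap between the libraries of the 2 groups. Of a passing L and S pair, the copy with the smaller p stood for both. It added up to 3 called members with the largest change from 9 of the lists and from any list past camera's threshold, or the member with the highest level as a value where none was called. For Ptf1a against the mutant or Neurog2 it added up to 2 from 4 lists. Not every gene so named is printed.

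The test was checked on simulated counts with known changes. All counts were drawn independently for each library from the group means and dispersions of the real data. They therefore lack the pairing of replicates described below. In the Ptf1a comparison at 6 h it called 4 of 67 genes changed 2-fold (5.97%), 28 of 67 changed 4-fold (41.8%) and 43 of 66 changed 16-fold (65.2%), and 3 of its 84 calls were false (3.57%). At 25 h it called 2 of 67 (2.99%), 28 of 67 (41.8%) and 47 of 66 (71.2%), and 4 of 82 calls were false (4.88%). With as few changed genes as in these simulations, changes of 2-fold were mostly missed. Where many genes change, the adjustment of p is less strict. With Ptf1a at 25 h in the real counts, 3011 of the 3609 higher genes were at least 2-fold, so smaller changes were called too.

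The alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, summed L and S counts, the replicate number as a block, a fit of the 8 libraries of a time or of the 2 groups compared, a minimum change of 2-fold and leaving out each library in turn. A group left with 1 library is assumed to vary like the others. Thinning every library to the smallest total and a block within each time were added after the data were seen. The deviations of replicate 1 from replicate 2 correlated across genes between all 28 pairs of groups, at 0.62 to 0.70 within 6 h, 0.20 to 0.37 within 25 h and 0.13 to 0.24 across times. The replicate number therefore pairs the libraries in these counts, and blocked counts are given beside the others. Unless a block is named, SEs, adjusted p values, list tests and leave-outs are of the fit without a block. They do not use this pairing, and a gene not called there may be called with a block. With 2 libraries per group, no test for an outlying library and no test on other splits of the samples was run. No library was left out of the main tests.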

Results

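Transcripts were counted in 16 libraries of Xenopus animal caps, which form epidermis when left alone. The caps carried mRNA for Ptf1a, Neurog2 or the Ptf1a mutant and were kept in dexamethasone, or served as controls, and were sampled at 6 h or 25 h with 2 libraries per group. In units of 1e6, the total counts at 6 h were 228.3 and 105.0 with Ptf1a, 55.5 and 31.7 with Neurog2, 86.3 and 64.7 with the mutant and 49.2 and 31.4 in the controls. At 25 h they were 62.4 and 105.3 with Ptf1a, 65.7 and 48.6 with Neurog2, 41.2 and 83.9 with the mutant and 72.8 and 34.7 in the controls. The first principal component held 76.1% of the variance and separated the times, and the second held 6.9%. Across genes, log2 CPM of the 2 libraries of a group correlated at 0.959 to 0.971, and genes are not independent replicates. The counts of replicates differed by far more than counting error, with a chi-square per degree of freedom of 40.6 to 159. The keratin krt5.7.S took 2.42 to 4.51% of all counts in each library of 25 h, where the 10 most abundant genes held 10.9 to 19.8%, against 1.87 to 2.59% at 6 h.

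The injected transcripts were read out first, as a check of the labels. At 6 h ptf1a.L (chromosome 6L, 23341343 to 23343013) stood at 183 ± 2.28 CPM in the Ptf1a caps and 149 ± 4.19 CPM in the mutant caps, against 0.174 ± 0.0183 CPM in the controls (SD, n = 2 here and throughout). By 25 h it was at 3.11 ± 1.06 and 5.67 ± 1.97 CPM in these caps. Counts do not tell the injected transcript from the embryo's own. In the Neurog2 caps neurog2.L (chromosome 1L, 61907027 to 61909892) stood at 175 ± 23.7 CPM at 6 h and 10.8 ± 1.93 CPM at 25 h, against 0.315 ± 0.082 and 0.178 ± 0.199 CPM in the controls. With Ptf1a, neurog2.L rose at 25 h to 5.64 ± 0.532 CPM (log2 fold change 5.32 ± 0.567, 4.14 to 7.17 over the alternatives, adjusted p = 0.000185), while the mutant caps held 0.0767 ± 0.0622 CPM. Transcripts of rbpj, the partner of Ptf1a in its DNA-bound complex, were not called in any of the 6 comparisons with the control. Their log2 fold changes ran from -0.30 to 0.32 for rbpj.L and from -0.27 to 0.06 for rbpj.S. Of the 11 measured construct and cofactor genes, 7 rose and 1 fell with Ptf1a at 25 h (7 and 1 adjusted over the list alone).

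**Figure D1:**
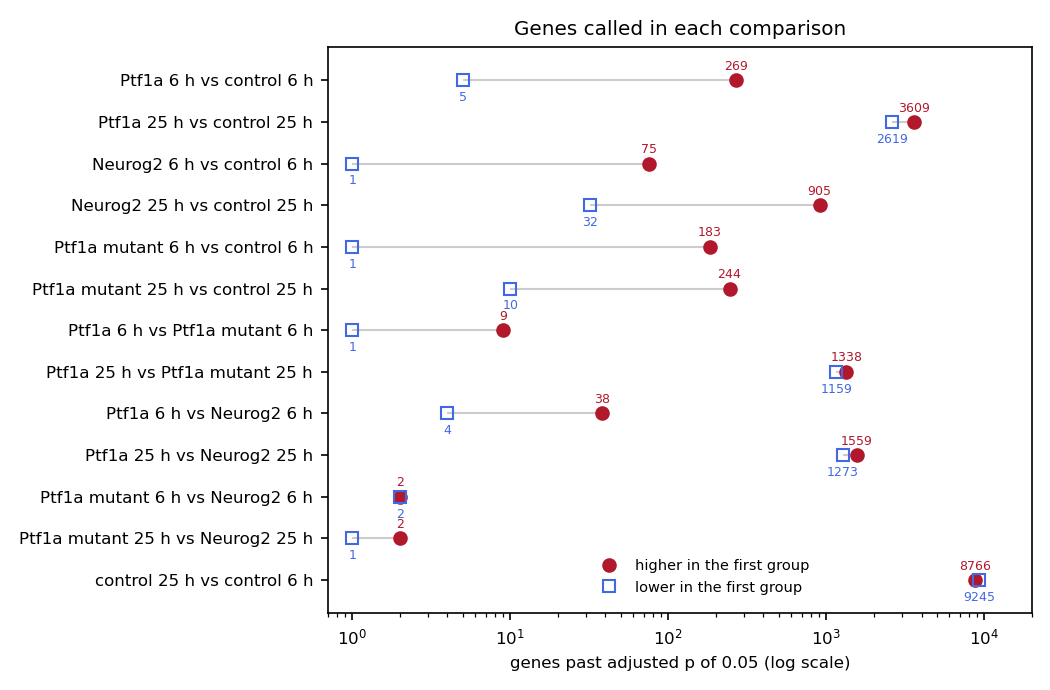
Number of genes past an adjusted p of 0.05 in each comparison of 2 groups, on a log axis, with filled circles for genes higher and open squares for genes lower in the group named first. Ptf1a caps of 25 h differ from their controls in 3609 and 2619 genes, Neurog2 caps in 905 and 32 and mutant caps in 244 and 10.

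Between 6 h and 25 h the control caps changed more than any other pair of groups compared. Of 24 measured ionocyte and small secretory cell genes 21 rose and 2 fell (22 and 2 adjusted over the list alone), with a median log2 fold change of 5.36. Among 48 multiciliated cell genes 40 rose and 5 fell (the same counts adjusted over the list alone), and among 74 epidermis genes 50 rose and 6 fell (50 and 7). Of 69 cell cycle genes 56 fell and 4 rose (56 and 4), and of 48 neural plate genes 31 fell and 3 rose (31 and 3). With the preset correlation these 5 lists passed camera at adjusted p = 7.44e-06, 6.2e-11, 1.42e-08, 4.79e-12 and 0.000109. None held with an estimated correlation, at adjusted p = 0.381 for the first 3 and 0.361 for the others. The ciliary genes tcte1.L and lrrc34.L were at least 1150-fold and 1400-fold higher at 25 h, and the early embryonic growth factor gene tdgf1.1.L and the neural plate factor foxd4l1.2.L at least 442-fold and 257-fold lower. In all, 8766 genes were higher and 9245 lower at 25 h, and leaving out any of the 4 control libraries left 7375 to 7795 and 7551 to 8153.

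At 6 h Ptf1a caps were compared with the controls to find its early response. Among the largest rises was that of prdm13.S (chromosome 5S, 65016308 to 65022315), a regulator of inhibitory neuron fate, from 0.0394 ± 0.0103 to 76.4 ± 27.1 CPM (log2 fold change 10.90 ± 1.36, adjusted p = 0.00181). Its homeolog prdm13.L was at least 634-fold higher. The neuronal factors ebf2.L (35.2 ± 15.4 against 0.0803 ± 0.114 CPM) and pou3f1.L (17.6 ± 3.49 against 0.0482 ± 0.0682 CPM) rose too, as did the corepressor cbfa2t2.S, from 0.774 ± 0.0266 to 149 ± 64.9 CPM. Of the 54 measured members of the neuronal transcription factor cascade 11 rose (25 adjusted over the list alone), and of the 36 Notch genes 7 rose (18 adjusted over the list alone). Among the latter, the Notch ligand gene dll1.S rose from 2.83 ± 1.82 to 37.5 ± 1.21 CPM (log2 fold change 3.72 ± 0.409, 3.21 to 4.63 over the alternatives, adjusted p = 0.000736), and numbl.L from 1.52 ± 0.628 to 35.6 ± 8.85 CPM. The epithelial-to-mesenchymal factor snai2.L rose from 0.149 ± 0.119 to 11.5 ± 3.97 CPM and gata3.L from 0.559 ± 0.527 to 8.40 ± 0.0025 CPM. The pan-neuronal RNA-binding gene elavl3.S was among 2 of 57 pan-neuronal genes that rose (2 adjusted over the list alone), at 26.4 ± 5.48 against 0.986 ± 0.174 CPM. No inhibitory neurotransmitter gene of 15 was called, and gad1.2.L, a gene of GABA synthesis, stood at 514 ± 144 CPM against 428 ± 115 in the controls (log2 fold change 0.26 ± 0.519, adjusted p = 1).

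Over all genes, 269 were higher and 5 lower with Ptf1a at 6 h, and 416 and 17 with the replicate block. A block within each time, here and below added after the data were seen, gave 686 and 55. A fit of the 8 libraries of 6 h gave 97 higher genes and a fit of the 4 libraries compared 7. The lower genes were the AP-1 genes fosl2.S (6.64 ± 0.538 against 22.4 ± 1.05 CPM) and junb.L, with adamts1.L, apobec2.L and sox7.L (log2 fold change -1.56), the last chosen after its value was seen. The Notch list (median log2 fold change 1.06) passed camera at adjusted p = 2.19e-14 and held with an estimated correlation at adjusted p = 0.0335. The cascade, with a median of 1.27 (1.24 with genes absent from a group at their bound), had the same preset value and an adjusted p = 0.43 with an estimated correlation. Inhibitory fate factors (4 of 41 rose, 6 adjusted over the list alone, adjusted p = 0.00329) and neural crest genes (5 of 29, 6 alone, adjusted p = 0.00544) gave adjusted p = 0.75 and 0.43 with an estimated correlation. The epidermis list was higher too (2 of 74 rose, 9 adjusted over the list alone, median 0.47) at adjusted p = 4.41e-06, and at adjusted p = 0.75 with an estimated correlation. Leaving out Ptf1a replicate 1, Ptf1a replicate 2, control replicate 1 and control replicate 2 gave 213, 124, 91 and 84 higher and 2, 1, 3 and 2 lower genes. Of the 27 called genes named by the rule, 20, 17, 12 and 12 stayed called without these libraries, and 9 in every case: ptf1a.L, prdm13.S, pou3f1.L, cbfa2t2.S, gata3.L, numbl.L, dll1.S, snai2.L and fosl2.S. DESeq2 size factors moved the median of all genes in this comparison from 0.151 to 0.002 on the log2 scale, so the changes given here stand about 0.151 above a scale with no median shift.

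Of the 75 genes higher in the Neurog2 caps at 6 h, 60 were among the 269 higher with Ptf1a. The Notch ligand gene dll1.S (chromosome 5S, 41566190 to 41573528) rose to 53.5 ± 8.13 CPM (log2 fold change 4.23 ± 0.418, 3.70 to 5.12 over the alternatives, adjusted p = 0.000942), cbfa2t2.S to 38.4 ± 13.0 CPM, the neuronal zinc finger gene myt1.L from 7.73 ± 0.181 to 141 ± 20.9 CPM and elavl3.S to 51.6 ± 10.9 CPM. In the mutant caps dll1.S reached 65.2 ± 5.03 CPM (log2 fold change 4.51 ± 0.423, 3.99 to 5.41 over the alternatives, adjusted p = 0.000479), cbfa2t2.S 110 ± 31.0 CPM, pou3f1.L 4.08 ± 1.87 CPM and id2.L, an inhibitor of bHLH factors, 280 ± 103 against 42.4 ± 5.01 CPM. Of the neuronal cascade 7 of 54 members rose with Neurog2 (20 adjusted over the list alone) and 11 with the mutant (22 adjusted over the list alone). Of the Notch list 4 of 36 and 7 of 36 rose (7 and 10 adjusted over the list alone), which held with an estimated correlation at adjusted p = 0.0378 and 0.0343. For the cascade the preset test gave adjusted p = 3e-25 and 7.2e-17, and an estimated correlation gave adjusted p = 0.125 and 0.437. Inhibitory fate factors had 0 of 41 called members with Neurog2 and 2 with the mutant, lhx1.S at 16.7 ± 10.6 CPM and gata3.L at 5.21 ± 1.60 CPM (2 and 5 adjusted over the list alone). As a list they missed camera's threshold (adjusted p = 0.0694 and 0.108, and adjusted p = 0.735 and 0.772 with an estimated correlation). They passed it for Neurog2 with the replicate block (adjusted p = 0.0345), and for both with a block within each time (adjusted p = 0.0112 and 0.0337) and without a filter on low counts (adjusted p = 0.0418 and 0.0261), and for the mutant with DESeq2 size factors (adjusted p = 0.0417). The epidermis list passed at adjusted p = 2.92e-06 with Neurog2 (1 of 74 rose, 2 alone, median 0.30) and 2.58e-06 with the mutant (none called, 4 alone, median 0.45). With an estimated correlation it gave adjusted p = 0.589 and 0.678. Neural crest genes rose in 2 of 29 and 3 of 29 cases (4 each alone) at adjusted p = 0.0271 and 0.0173, and adjusted p = 0.464 and 0.437 with an estimated correlation. The glucocorticoid target gene tsc22d3.L rose with all 3 fusions, to 114 ± 30.2 CPM with Ptf1a, 97.8 ± 15.7 with Neurog2 and 162 ± 11 with the mutant, from 9.94 ± 3.69 CPM. The globin gene hbg1.L was at least 232-fold higher in the Neurog2 caps, at 6.73 ± 0.738 CPM.

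Neurog2 gave 75 higher genes and 1 lower at 6 h, apobec2.L, and the mutant 183 higher and 1 lower, fosl2.S. The replicate block gave 103 and 1 for Neurog2 and 288 and 3 for the mutant, and a block within each time 149 and 7 and 525 and 8, while a fit of the 8 libraries of 6 h gave 24 and 66 higher genes and fits of the 4 libraries compared 2 and 12. With all libraries 1194 genes had an unadjusted p under 0.05 with Neurog2, a smaller share than the 0.05 expected without any change. By DESeq2 7 genes were lower. Without any 1 of the 4 libraries compared, fewer genes were higher with Neurog2, and fewer of the 18 named genes stayed called. Those called each time were neurog2.L, cbfa2t2.S, dll1.S and tsc22d3.L. Without mutant replicate 1, mutant replicate 2, control replicate 1 and control replicate 2 the mutant gave 83, 387, 59 and 52 higher and 0, 1, 0 and 0 lower genes, and 10, 20, 11 and 7 of 21 named genes stayed called. Among these, ptf1a.L, mxra7.L, cbfa2t2.S, zc3h12c.S, pou3f1.L, dll1.S and id2.L were called each time. For tsc22d3.L the adjusted p was 0.000135 with Ptf1a, 0.000942 with Neurog2 and 8.64e-05 with the mutant.

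**Figure D2:**
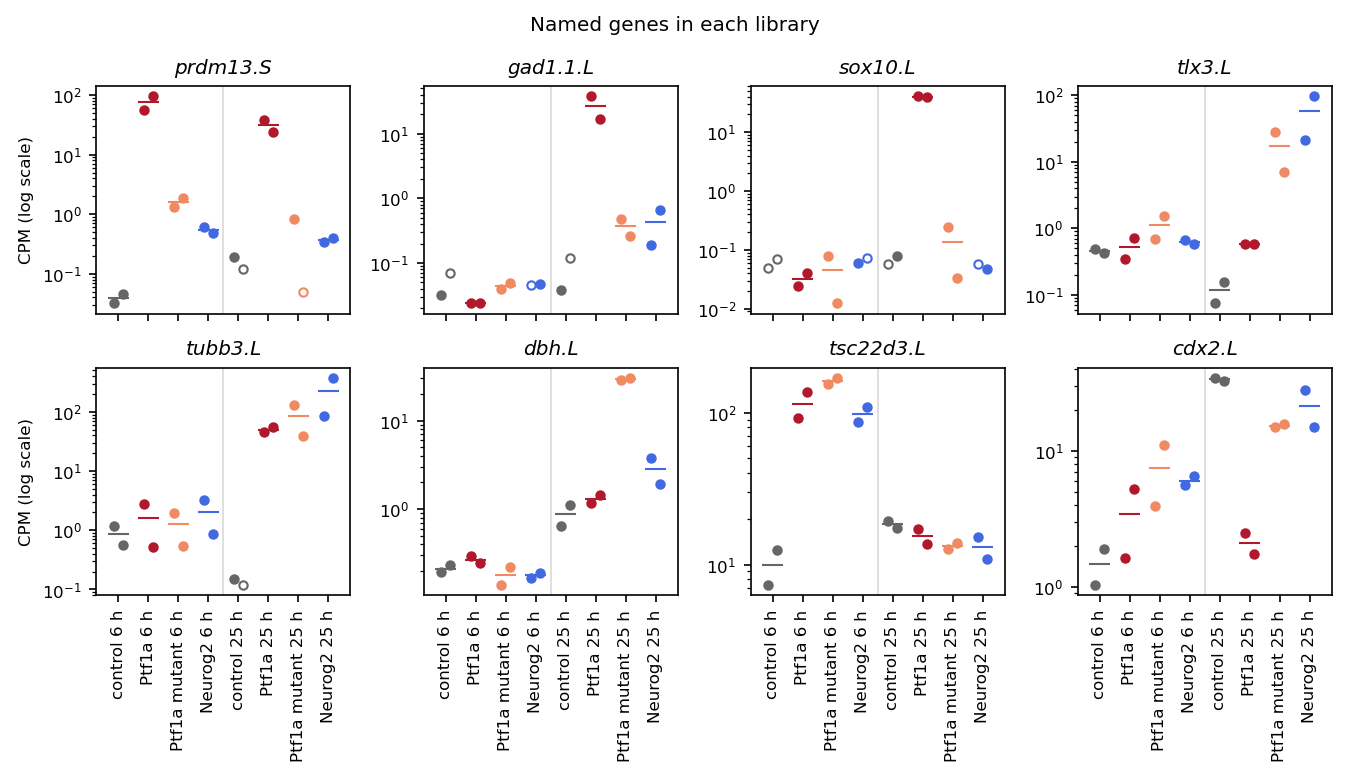
CPM of 8 named genes in each library, on log axes, with a line at the mean of a group and open circles for libraries with 0 counts, drawn at 3 counts. sox10.L stands at 40 CPM in Ptf1a caps of 25 h and near the floor elsewhere, while dbh.L is highest in mutant caps at 29.5 CPM.

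At 25 h the Ptf1a caps held a broad neuronal programme. Of 57 measured pan-neuronal genes 41 rose and none fell (41 and 1 adjusted over the list alone). The neuronal tubulin gene tubb2b.S went from 0.467 ± 0.129 to 282 ± 14.3 CPM (log2 fold change 9.30 ± 1.11, adjusted p = 0.00031, and 4.74 with both tubb2b copies summed), and stmn2.L, the splicing factor gene nova2.S and ina.S were at least 319-fold, 780-fold and 158-fold higher. Of 41 inhibitory fate factors 31 rose and none fell (32 and 1 adjusted over the list alone), among them lhx1.S, tal1.L and the enkephalin gene penk.L, at least 174-fold, 41.3-fold and 38.8-fold higher. Of 15 inhibitory neurotransmitter genes 8 rose and 2 fell (10 and 2 adjusted over the list alone). The GABA synthesis gene gad1.1.L (chromosome 9_10L, 65208328 to 65232654) stood at 27.2 ± 14.9 against 0.0188 ± 0.0266 CPM, a count ratio of 997 (276 to 8240), and slc32a1.S, the vesicular GABA and glycine transporter gene, was at least 100-fold higher. Another gene of GABA synthesis, gad1.2.L, went the other way between the times. The effect of Ptf1a on it differed from that at 6 h by -2.75 ± 0.748 on the log2 scale (adjusted p = 0.0382 in the test of the difference). Excitatory and glutamatergic genes rose in 13 of 40 cases (15 adjusted over the list alone), with pou4f1.L at 13.6 ± 3.78 against 0.0774 ± 0.00317 CPM. Sensory neuron genes rose in 19 of 47 cases and fell in 2 (23 and 3 alone), with peripherin, prph.S, at 352 ± 74.1 against 0.561 ± 0.00436 CPM.

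Neural crest and progenitor genes rose in the same caps. Of 29 neural crest genes 20 rose and 1 fell (21 and 2 adjusted over the list alone), with foxd3.L at least 127-fold higher and sox10.L (chromosome 4L, 114982869 to 114991299) at 40 ± 0.934 against 0.0398 ± 0.0563 CPM, a count ratio of 1560 (432 to 12900). Of 48 neural plate genes 24 rose and 2 fell (33 and 2 adjusted over the list alone), irx1.L to 50.5 ± 8.02 from 0.115 ± 0.05 CPM. Notch genes rose in 23 of 36 cases (23 up and 1 down adjusted over the list alone), hes5.2.L by at least 49.8-fold. Of 69 cell cycle genes 20 rose and 4 fell (23 and 5 alone), mcm4.S to 24.6 ± 0.681 from 3.38 ± 0.832 CPM.

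Genes of ciliated and other epidermal cells moved the opposite way. Of 48 multiciliated cell genes 35 fell and none rose (36 and 0 adjusted over the list alone). The centrin gene cetn4.L stood at 4.84 ± 0.939 against 40 ± 1.45 CPM (log2 fold change -3.05 ± 0.336, adjusted p = 0.000221) and ccno.S, a gene of centriole amplification, at 0.329 ± 0.186 against 2.80 ± 0.131 CPM. Of 24 ionocyte and small secretory cell genes 16 fell and 2 rose (17 and 2 adjusted over the list alone), the carbonic anhydrase gene ca12.L to 9.84 ± 5.99 from 73.7 ± 6.28 CPM. The 2 that rose were foxi2.L and foxi2.S, copies of a factor gene, at 27.3 ± 11.7 against 2.06 ± 0.216 and 14.5 ± 1.96 against 0.295 ± 0.258 CPM. Of 74 epidermis genes 19 fell and 5 rose (21 and 5 adjusted over the list alone), with the hyaluronan synthase gene has1.S at 175 ± 83.0 against 1050 ± 247 CPM, and krt19.S rising to 515 ± 126 from 75.0 ± 7.98 CPM. With both krt19 copies summed the change of krt19 was -0.35. The posterior factor gene cdx2.L stood at 2.11 ± 0.534 against 33.6 ± 1.11 CPM.

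With Ptf1a at 25 h 3609 genes were higher and 2619 lower, and 4665 and 3620 with the replicate block (5875 and 4994 with a block within each time). The share of higher genes among those called was 57.9%, against 48.3% with DESeq2 size factors (3132 higher and 3350 lower) and 47.7% in the DESeq2 Wald test (3935 and 4310). The lists given above for these caps passed camera with the preset correlation, and none held with an estimated one. Multiciliated cell genes (median log2 fold change -2.26) had adjusted p = 3.93e-25 preset and 0.0582 estimated, inhibitory fate factors (median 5.88, 5.41 with bounds) 1.74e-14 and 0.0582, and pan-neuronal genes (5.24 with bounds) 7.8e-14 and 0.238. The estimated values were adjusted p = 0.0582 for neural crest, neural plate and Notch genes, 0.13 for inhibitory neurotransmitter, 0.238 for excitatory, 0.249 for sensory, 0.28 for cell cycle, 0.164 for ionocyte and 0.368 for epidermis genes. Without Ptf1a replicate 1, Ptf1a replicate 2, control replicate 1 and control replicate 2 the higher counts were 2292, 2772, 1689 and 1886 and the lower ones 1369, 1874, 1270 and 1437. Without these libraries 52, 51, 37 and 46 of the 57 called named genes stayed called, and 37 in every case, gad1.1.L, sox10.L, lhx1.S, tubb2b.S, prph.S, foxd3.L, cetn4.L, ccno.S, ca12.L, has1.S and cdx2.L among them.

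**Figure D3:**
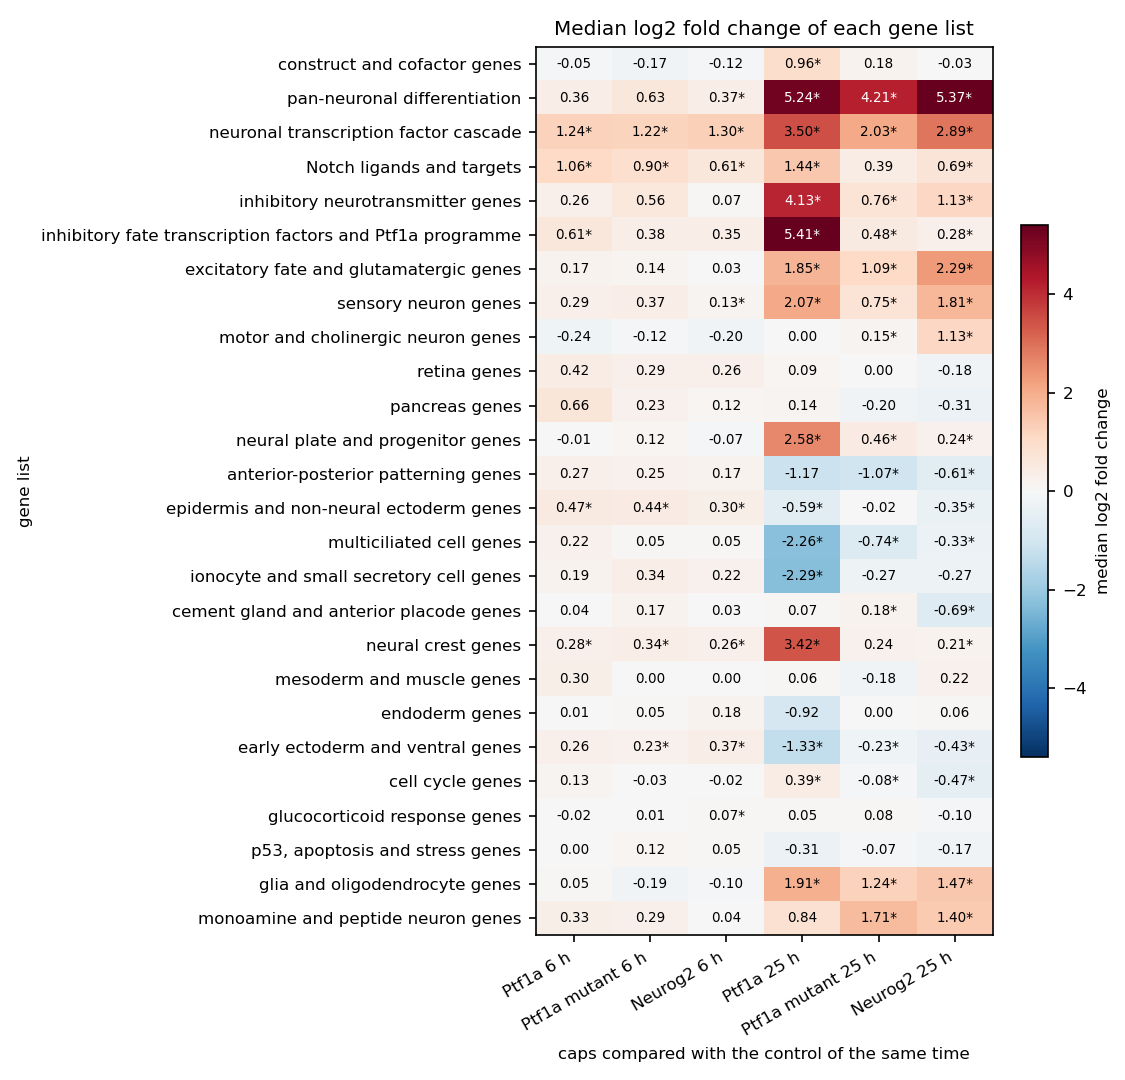
Median log2 fold change of each of 26 gene lists (vertical axis) in each group of injected caps against its control (horizontal axis), with genes absent from a group at their bound and stars for an adjusted camera p under 0.05 with the preset correlation. At 25 h the inhibitory fate factors have a median of 5.41 with Ptf1a, 0.48 with the mutant and 0.28 with Neurog2.

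Neurog2 caps at 25 h held pan-neuronal and excitatory genes. Of 57 pan-neuronal genes 38 rose and none fell (47 and 0 adjusted over the list alone), with the neuronal tubulin gene tubb3.L at 228 ± 203 against 0.0752 ± 0.106 CPM (log2 fold change 11.16 ± 1.56, adjusted p = 0.00467) and stmn2.L at least 926-fold higher. For tubb3.L 1 control library had no counts, and without the other the fitted change was 17.07 (adjusted p = 0.0899). Of the 54 cascade members 28 rose (40 adjusted over the list alone), neurod1.L to 46.6 ± 46.9 CPM. Of 40 excitatory and glutamatergic genes 11 rose (14 adjusted over the list alone), with tlx3.L, a switch gene of excitatory fate, at 59.0 ± 53 against 0.117 ± 0.0595 CPM and drgx.L at 54.5 ± 43.1 CPM, a count ratio of 2000 (552 to 16500). Sensory genes rose in 14 of 47 cases (20 adjusted over the list alone), prph.S to 368 ± 313 CPM, and monoamine and peptide genes in 5 of 26 (9 up and 2 down alone), the tyrosine hydroxylase gene th.S to 31.1 ± 14.3 from 1.19 ± 0.349 CPM. Of 41 inhibitory fate factors 2 rose, skor2.L and sall3.L (8 up and 1 down adjusted over the list alone), and of 15 inhibitory neurotransmitter genes 1, slc6a13.L (4 alone). Both lists passed camera, at adjusted p = 0.0154 and 0.0113 (adjusted p = 0.376 and 0.232 with an estimated correlation). No multiciliated cell gene was called among 48, though as a list they passed camera at adjusted p = 6.73e-05 (median -0.33, adjusted p = 0.348 with an estimated correlation). The cell cycle list, with none of 69 called (median -0.47), was lower at adjusted p = 4.88e-10, and adjusted p = 0.188 with an estimated correlation. The epidermis list, with 1 of 74 lower (none alone, median -0.35), was lower at adjusted p = 2.92e-05, and adjusted p = 0.338 with an estimated correlation.

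With Neurog2 at 25 h 905 genes were higher and 32 lower, and 1196 and 131 with the replicate block (1716 and 441 with a block within each time). A fit of the 8 libraries of 25 h gave 240 and 0, and a fit of the 4 libraries compared 0 and 0, by edgeR. With all libraries 3685 genes had an unadjusted p under 0.05, and DESeq2 gave 1511 and 322. Camera gave adjusted p = 9e-46 for pan-neuronal, 1.14e-25 for cascade, 1.82e-12 for excitatory, 4.75e-14 for sensory and 1.77e-05 for monoamine genes, and adjusted p = 0.0888 for each of them with an estimated correlation. The 2 Neurog2 libraries differed widely, as the SDs show. Without Neurog2 replicate 1, Neurog2 replicate 2, control replicate 1 and control replicate 2 the higher counts were 1320, 201, 11 and 32, the lower ones 99, 0, 1 and 0, and 36, 21, 4 and 6 of 41 named genes stayed called. Those that did in every case were neurog2.L, prph.S, ncam1.L (137 ± 74.9 against 2.36 ± 0.261 CPM) and th.S.

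Neuronal genes rose in mutant caps at 25 h too, with fewer called than in the Ptf1a or Neurog2 caps. Fewer calls are no test of a difference, and the direct comparisons below called few or no pan-neuronal genes. Adjusted over the list alone, as many pan-neuronal genes rose as with Ptf1a. Of 57 pan-neuronal genes 25 rose and none fell (41 and 0 adjusted over the list alone), tubb3.L to 85.9 ± 67.2 CPM. Monoamine and peptide genes rose in 5 of 26 cases (8 adjusted over the list alone). Among them were chga.L (chromosome 8L, 65168898 to 65184893), which encodes chromogranin A of secretory granules, at 119 ± 27.1 against 2.29 ± 1.49 CPM (log2 fold change 5.73 ± 0.431, 4.56 to 6.58 over the alternatives, adjusted p = 0.000392), and the noradrenaline synthesis gene dbh.L at 29.5 ± 0.948 against 0.877 ± 0.337 CPM. Excitatory genes rose in 5 of 40 cases (12 adjusted over the list alone), tlx3.L to 17.4 ± 14.6 CPM, and sensory genes in 6 of 47 (14 adjusted over the list alone), prph.S to 182 ± 135 CPM. Of 41 inhibitory fate factors 1 rose, sall3.S (2 up and 1 down adjusted over the list alone), and of 15 inhibitory neurotransmitter genes 1 (4 alone). Both lists passed camera, at adjusted p = 0.0404 and 0.00397 (adjusted p = 0.565 and 0.187 with an estimated correlation). The keratin gene krt19.S rose to 336 ± 113 CPM, while the change of both krt19 copies summed was -0.03. None of 48 multiciliated cell genes was called, with dnah9.S at 162 ± 91.9 against 291 ± 77.8 CPM. As a list they passed camera at adjusted p = 3.2e-24 (median -0.74, adjusted p = 0.0879 with an estimated correlation).

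With the mutant at 25 h 244 genes were higher and 10 lower, and 367 and 42 with the replicate block (586 and 193 with a block within each time). A fit of the 8 libraries of 25 h gave 7 and 0, and a fit of the 4 libraries compared 0 and 0, by edgeR. With all libraries 2751 genes had an unadjusted p under 0.05, and DESeq2 gave 749 and 201. The monoamine and peptide list passed camera at adjusted p = 1.82e-13 and held with an estimated correlation at adjusted p = 0.00415. The pan-neuronal list had 2.02e-36 preset and an adjusted p = 0.0879 with an estimated correlation, and the excitatory and sensory lists had 4.25e-07 and 4.91e-09 preset and an adjusted p = 0.187 each with an estimated one. Without mutant replicate 1, mutant replicate 2, control replicate 1 and control replicate 2 the higher counts were 40, 436, 1 and 2, the lower ones 1, 46, 0 and 0, and 13, 26, 1 and 2 of 30 named genes stayed called. Of these only chga.L did in every case.

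Wild-type and mutant Ptf1a were compared directly at 25 h. The Ptf1a caps were higher in 20 of 41 inhibitory fate factors and lower in none (29 and 0 adjusted over the list alone), with the nephrin-like gene kirrel2.L (chromosome 7L, 122454846 to 122472634) at 49.4 ± 2.44 against 0.0931 ± 0.039 CPM (log2 fold change 9.12 ± 0.614, 8.11 to 9.52 over the alternatives, adjusted p = 7.61e-05). Also higher were 6 of 15 inhibitory neurotransmitter genes (8 up and 2 down alone), gad1.1.L among them at 27.2 ± 14.9 against 0.372 ± 0.156 CPM, and 12 of 29 neural crest genes (19 up and 1 down alone), with sox10.L at 40 ± 0.934 against 0.137 ± 0.148 CPM. Lower in the Ptf1a caps were tlx3.S (0.467 ± 0.165 against 25.1 ± 21.4 CPM), dbh.L (1.31 ± 0.198 against 29.5 ± 0.948 CPM) and the adrenaline synthesis gene pnmt.L (0.426 ± 0.137 against 7.69 ± 1.44 CPM). Of 57 pan-neuronal genes 4 were higher (4 adjusted over the list alone), and tubb3.L differed by less than its error (log2 fold change -0.77 ± 0.924, adjusted p = 0.68). Of 48 multiciliated cell genes 26 were lower with Ptf1a (1 up and 33 down alone).

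In that comparison 1338 genes were higher with Ptf1a and 1159 lower, and 2280 and 2168 with the replicate block (3579 and 3696 with a block within each time). The inhibitory fate (preset adjusted p = 4.53e-18), neural crest, neural plate and Notch lists held with an estimated correlation at adjusted p = 0.0262, while inhibitory neurotransmitter and multiciliated genes gave adjusted p = 0.1. Without Ptf1a replicate 1, Ptf1a replicate 2, mutant replicate 1 and mutant replicate 2 the higher counts were 574, 971, 925 and 235, the lower ones 207, 707, 871 and 158, and 10, 10, 10 and 8 of 14 named genes stayed called. Among those that did each time were kirrel2.L, sox10.L, tlx3.S, dbh.L, pnmt.L and gad1.1.L. At 6 h 9 genes were higher with Ptf1a, snai2.L (11.5 ± 3.97 against 0.179 ± 0.0279 CPM) and post.S (58.7 ± 29.4 against 2.52 ± 0.0457 CPM) among them, and 1 was lower, nhsl2.L (2.69 ± 0.423 against 9.12 ± 0.24 CPM). With all libraries 500 genes had an unadjusted p under 0.05 there, a smaller share than the 0.05 expected without any change. By DESeq2 6 genes were lower. The replicate block gave 19 and 1 and a block within each time 57 and 7. In each of the same leave-outs nhsl2.L lost the call. Of the 5 named genes 4, 3, 3 and 2 stayed called, snai2.L and post.S each time. For prdm13.S the difference at 6 h was not called (log2 fold change 5.57 ± 0.985, adjusted p = 0.135), though 1.61 ± 0.399 CPM in the mutant caps stood against 76.4 ± 27.1 CPM.

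**Figure D4:**
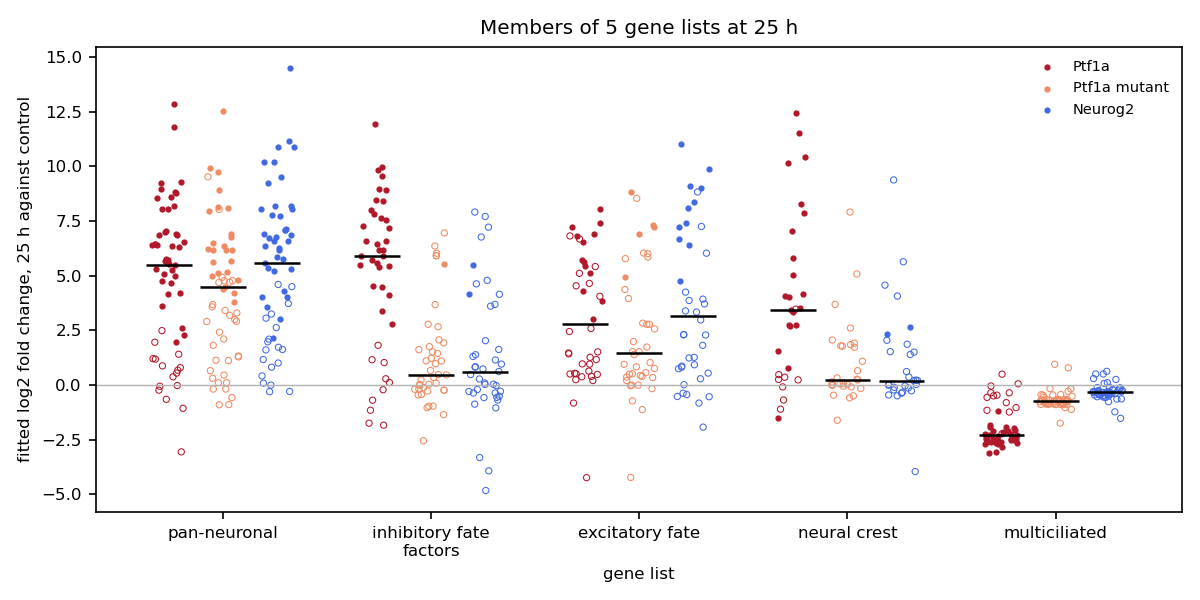
Fitted log2 fold change against the control at 25 h of each measured member of 5 gene lists, filled where called and open where not, with a bar at the median of each list. The multiciliated cell genes have a median of -2.26 with Ptf1a, -0.74 with the mutant and -0.33 with Neurog2, and fitted values of genes absent from the controls are no bounds.

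Ptf1a and Neurog2 caps differed at 25 h along similar lines. Of 41 inhibitory fate factors 21 were higher with Ptf1a and none lower (28 and 0 adjusted over the list alone), dmbx1.L at 16.5 ± 2.46 against 0.0238 ± 0.0337 CPM, a count ratio of 799 (221 to 6600). The GABA synthesis gene gad1.1.L stood at 27.2 ± 14.9 against 0.427 ± 0.338 CPM (log2 fold change 6.01 ± 0.86, 4.21 to 7.16 over the alternatives, adjusted p = 0.00178), and foxd3.S of the neural crest was at least 189-fold higher. Excitatory genes were lower with Ptf1a in 7 of 40 cases and higher in 2 (the same counts adjusted over the list alone), with tlx3.L at 0.588 ± 0.00604 against 59.0 ± 53 CPM and tlx3.S (chromosome 3S, 113467985 to 113476499) at 0.467 ± 0.165 against 56.6 ± 46.4 CPM. Of 57 pan-neuronal genes 1 was higher and 4 lower (1 and 5 adjusted over the list alone), of 69 cell cycle genes 28 higher (48 up and 1 down alone), and of 48 multiciliated cell genes 30 lower (38 alone). Genes higher with Ptf1a numbered 1559 and lower ones 1273, and 2578 and 2166 with the replicate block (3868 and 3635 with a block within each time). The inhibitory fate list held with an estimated correlation at adjusted p = 0.0472 and the neural plate and neural crest lists at 0.0428, while multiciliated genes gave adjusted p = 0.0666 and cell cycle genes 0.0742. Without Ptf1a replicate 1, Ptf1a replicate 2, Neurog2 replicate 1 and Neurog2 replicate 2 the higher counts were 1072, 991, 554 and 802, the lower ones 458, 607, 492 and 798, and 10, 8, 10 and 8 of 14 named genes stayed called, foxd3.S, sox10.L, dmbx1.L, tlx3.S, tlx3.L, gad1.1.L and sst.S each time.

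At 6 h 38 genes were higher with Ptf1a than with Neurog2 and 4 lower, and 70 and 6 with the replicate block (154 and 20 with a block within each time). Higher were prdm13.S (76.4 ± 27.1 against 0.54 ± 0.0845 CPM), snai2.L (11.5 ± 3.97 against 0.39 ± 0.128 CPM) and hes3.3.S (count ratio 424, 117 to 3500). The lower genes were neurog2.L, hbg1.L, hes2.L and arhgef3.2.S. Without Ptf1a replicate 1, Ptf1a replicate 2, Neurog2 replicate 1 and Neurog2 replicate 2 the counts were 37, 7, 7 and 7 higher and 2 lower each, and 6, 4, 3 and 4 of 9 named genes stayed called, ptf1a.L, hbg1.L and neurog2.L each time. The inhibitory fate list passed camera at adjusted p = 0.0339 (0.881 with an estimated correlation) and lost it with the replicate block, at 0.0773. DESeq2 size factors moved the median of all genes here from 0.122 to -0.016.

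Few genes were called between mutant and Neurog2 caps beyond the injected transcripts. Few calls do not show that the caps were alike, since neuronal genes such as tubb3.L differed widely between the libraries of each group at 25 h. At 6 h ptf1a.L and nhsl2.L (9.12 ± 0.24 against 2.2 ± 0.693 CPM) were higher with the mutant, and neurog2.L and hbg1.L lower. At 25 h agbl1.S (18.8 ± 1.65 against 0.979 ± 0.905 CPM) and dbh.L (29.5 ± 0.948 against 2.85 ± 1.34 CPM, log2 fold change 3.37 ± 0.419, adjusted p = 0.0402) were higher and neurog2.L lower. The cement gland list was higher with the mutant (0 of 16 members called, 6 adjusted over the list alone, median log2 fold change 0.36) and held with an estimated correlation at adjusted p = 0.0325. Pan-neuronal genes were lower as a list (median -1.09, adjusted p = 1.98e-20), with 0 of 57 called (6 alone) and an adjusted p = 0.146 with an estimated correlation. In all, 2 genes were higher and 2 lower at 6 h, and 2 and 1 at 25 h, while DESeq2 gave 51 and 10 at 6 h and 32 and 93 at 25 h. Without Neurog2 replicate 1, Neurog2 replicate 2, mutant replicate 1 and mutant replicate 2 the counts at 6 h were 1, 1, 1 and 7 higher and 1 lower each, and those at 25 h 3, 2, 0 and 1 higher and 57, 1, 1 and 1 lower, with ptf1a.L and neurog2.L called each time at 6 h and neurog2.L at 25 h, while dbh.L lost the call in 3 of these 4 cases. The replicate block gave 9 and 3 at 6 h and 4 and 1 at 25 h, and a block within each time 35 and 4 and 20 and 13.

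The sets of genes higher in the caps with the 3 fusions overlapped. At 6 h 54 genes were higher with all 3, among them dll1.S, cbfa2t2.S, pou3f1.L and tsc22d3.L, and at 25 h 213 were higher and 6 lower with all 3. Ptf1a and the mutant shared 140 higher genes at 6 h and 226 at 25 h, Ptf1a and Neurog2 60 and 758, and Neurog2 and the mutant 56 and 225. Independent lists of these sizes would share 1.62 and 29, 0.664 and 107, and 0.452 and 7.27. Lower in both at 25 h were 29 genes for Ptf1a and Neurog2, 9 for Ptf1a and the mutant and 6 for Neurog2 and the mutant. Opposite calls numbered 2, between Ptf1a and Neurog2 at 25 h. Across 21456 genes the fold changes of the pairs correlated at 0.76, 0.84 and 0.76 at 6 h (Ptf1a with Neurog2, Ptf1a with the mutant, Neurog2 with the mutant) and at 0.75, 0.77 and 0.88 at 25 h. Because the pairs share the 2 control libraries, simulated groups without any change correlated at 0.51 to 0.55. They shared no called gene in 10 draws. Hardly any gene of an unchanged group can be called, so this does not show how many shared calls the controls produce. The simulated libraries were drawn independently and lack the pairing of replicates, so the simulated correlation and covariance are only a rough baseline. The covariance beyond the simulated one was 0.2, 0.26 and 0.19 at 6 h and 1.11, 0.89 and 0.76 at 25 h. The 2 control libraries cannot be split, so part of the shared calls can come from them. The labels do not make plain what the controls received, so injection or dexamethasone may add to the shared calls too.

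The effects of Ptf1a differed between the times. In the test of the difference 1358 genes had a higher effect at 25 h than at 6 h and 1623 a lower one, and 2046 and 2643 with the replicate block (3048 and 4184 with a block within each time). For Neurog2 the counts were 63 and 27 (95 and 48 with the block, 206 and 141 with that within each time), and for the mutant 22 and 37 (36 and 96 with the block, 99 and 253 with that within each time). The neuronal genes nova2.S and neurog1.L gained with Ptf1a, while pou3f1.L, cbfa2t2.S and snai2.L rose at 6 h and had a lower effect at 25 h. Without replicate 1 and 2 of the Ptf1a caps of 6 h, the controls of 6 h, the Ptf1a caps of 25 h and the controls of 25 h, in this order, 615, 570, 767, 743, 843, 1072, 596 and 656 effects were higher and 868, 895, 1010, 797, 734, 1463, 807 and 842 lower. In the same order, Neurog2 gave 0, 0, 10, 19, 468, 24, 0 and 1 higher and 8, 3, 6, 5, 48, 8, 0 and 1 lower, by edgeR (2759 effects at an unadjusted p under 0.05 with all libraries, and 609 higher and 181 lower by DESeq2). The mutant gave 3, 15, 8, 11, 13, 56, 4 and 2 higher and 12, 97, 13, 16, 22, 34, 9 and 10 lower.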

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

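The tests of depth, mutant mRNA level, hormone response, shared bHLH activity and injected globin sequence were chosen after the results were seen, while the tests of a difference between the times were planned.

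The effect of Ptf1a against its control differed between 6 h and 25 h, higher at 25 h in 1358 genes and lower in 1623. Leaving out single libraries gave 570 (without Ptf1a replicate 2 of 6 h) to 1072 (without Ptf1a replicate 2 of 25 h) higher and 734 (without Ptf1a replicate 1 of 25 h) to 1463 (without Ptf1a replicate 2 of 25 h) lower. Values here are differences between the 2 log2 fold changes, each past an adjusted p of 0.05, not every such gene is given, and where a gene had 0 counts in a group they are no bounds. Neuronal genes gained by 25 h: neurog1.L 14.95, nova2.S 13.65, olig3.S 12.86, apc2.S 12.65, tal1.L 10.33, pou3f2.S 10.25, gad1.1.L 9.67, tubb2b.S 9, prph.S 8.75, lhx1.S 8.56, pou4f1.L 8.30, neurod1.L 8.18, neurog2.S 8.07 and neurog2.L 3.57. So did neural crest and progenitor genes: foxd3.L 12.39, sox10.S 10.77, cdh11.S 10.18, rfx4.L 9.53, irx1.L 7.67, nes.L 6.59 and sox3.S 2.46. Ectodermal and cell cycle genes with a higher effect at 25 h were foxi2.S 6.72, foxi2.L 4.66, foxi4.1.L 4.35, e2f1.S 3.91, mcm4.S 2.82 and krt19.S 2.79.

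Lower at 25 h was the effect of Ptf1a on early response genes: hes3.3.S -8.33, cbfa2t2.S -6.85, pou3f1.L -6.67, snai2.S -5.91, gata3.L -4.99, snai2.L -4.79, gata6.L -4.52 and numbl.L -3.27. For ptf1a.L, counted together from the injected mRNA and the embryo, the difference was -6.74. Epidermal, ciliary and ionocyte genes with a lower effect were tcte1.L -9.84, muc1.L -9.25, ccno.S -3.62, has1.S -3.62, dlx3.L -3.31, cetn4.L -3.09 and ca12.L -2.65. The others were hoxd1.L -10.34, prr15l.S -8.46, angptl4.S -8.36, cnr2.S -6.11, ankrd24.L -5.28, cdx2.L -5.22, gad1.2.L -2.75 and ccna1.S -2.60. Of the 8 genes the rule named for this test, 6 kept the call whichever library was left out. The exceptions were neurog1.L, kept in 7 of 8 cases, and hoxd1.L, kept in 2 of 8 and at -4.96 (adjusted p = 1) without control replicate 1 of 25 h.

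For Neurog2 63 effects were higher and 27 lower at 25 h, and 0 (without Neurog2 replicate 1 of 6 h, for example) to 468 (without Neurog2 replicate 1 of 25 h) and 0 to 48 with single libraries left out, by edgeR (2759 at an unadjusted p under 0.05, 609 and 181 by DESeq2). Higher were apc2.S 12.04, draxin.L 11.90, nova2.S 11.71, klhl35.S 11.33, adcyap1.L 9.91, tlx3.L 8.64, prph.S 8.61, th.S 4.80 and ncam1.L 4.75. Lower were hbg1.L -10.82, angptl4.S -8.17, snai2.S -6.96, zc3h12c.L -6.45, cbfa2t2.S -4.44, tsc22d3.L -3.81 and sox8.L -3.10. Of the 8 genes the rule named for this test (apc2.S, draxin.L, nova2.S, klhl35.S, hbg1.L, angptl4.S, snai2.S and zc3h12c.L), none kept the call in every leave-out, and in 6 of the 8 leave-outs none of them was called. For the mutant 22 effects were higher and 37 lower, and 2 (without control replicate 2 of 25 h) to 56 (without mutant replicate 2 of 25 h) and 9 (without control replicate 1 of 25 h) to 97 (without mutant replicate 2 of 6 h) with single libraries left out. Higher were klhl35.S 12.77, nova2.S 11.68, map1b.L 8.55, scg3.L 8.47, prph.S 7.73, chga.L 5.61, dbh.L 5.32, ncam1.L 3.98 and krt19.S 2.38. Lower were zc3h12c.L -6.96, cbfa2t2.S -6.47, ptf1a.L -5.60, nhsl2.L -5.36, dll1.S -3.51 and id2.L -2.73. Of the 8 named by the rule, cbfa2t2.S and nhsl2.L kept the call in every leave-out, scg3.L in 5 of 8, klhl35.S and zc3h12c.L in 3, map1b.L in 2, and nova2.S and ptf1a.L (adjusted p up to 0.587) in 1.

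Far more genes were called with Ptf1a at 25 h than with Neurog2 or the mutant. Depth as the whole cause is argued against: with every library thinned to the smallest total, 6253, 878 and 175 genes were called, and Ptf1a still had 7.12 times the calls of Neurog2. A wider spread between the other libraries stays open for a part of the difference: without Neurog2 replicate 1 the count of its higher genes was 1320 against 905, and without mutant replicate 2 that of the mutant was 436 against 244. A lower dose of the mutant mRNA may still contribute, as ptf1a.L in the mutant caps was 0.817 times that in the Ptf1a caps at 6 h with an interval of 0.395 to 1.69, and 1.81 times (0.845 to 3.86) at 25 h, and protein was not measured. The biological explanation, a loss of function through the changed residues, stays open beside it.

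The glucocorticoid target tsc22d3.L was higher with all 3 fusions at 6 h, and so was angptl4.S. The latter stood at only 0.174 to 0.749 CPM in the injected libraries and at 0 in the controls. Its more abundant copy angptl4.L stood at 3.63 and 3.55 CPM with Neurog2 against 3.6 and 4.52 CPM in the controls. With Ptf1a angptl4.L stood at 17.4 and 19.1 CPM and with the mutant at 25.7 and 23.6 CPM, without a call. Summed copies gave -0.06 with Neurog2. The call of angptl4.S was lost with Neurog2 and the mutant without either control library or without replicate 1 of the injected caps, and with Ptf1a without control replicate 1. A difference in hormone response between injected and control caps may be the reason for these rises. It stays open, since the labels do not make plain whether the controls received dexamethasone. Of the 24 measured response genes 10 moved by less than 0.5 on the log2 scale in all 3 comparisons. The list test passed with Neurog2 alone (preset adjusted p = 0.015), and lost that with a block within each time (adjusted p = 0.0536). Without a filter on low counts it passed with the mutant too (adjusted p = 0.0431). With an estimated correlation it held in 0 of 3. These values do not exclude a difference in hormone response, since a few targets can carry it. If the genes answered to the shared bHLH activity they could be higher at 25 h too, and 0 of the 2 were called then with any fusion, by edgeR. That outcome decides little, because transcripts of the injected genes were far lower by 25 h. In CPM ptf1a.L fell 58.7-fold in the Ptf1a caps and 26.4-fold in the mutant caps, and neurog2.L 16.1-fold in the Neurog2 caps. These counts include the embryo's own transcripts.

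The globin gene hbg1.L was higher in the Neurog2 caps at 6 h and not with the other fusions. Globin sequence in the injected Neurog2 mRNA is a candidate explanation: less the control level, hbg1.L fell 18.4-fold between 6 h and 25 h and neurog2.L 16.4-fold, and hbg1.L stood at 3.93 and 3.78% of neurog2.L in the 2 libraries. The vector of this mRNA is not given. Blood cells would raise other globin and erythroid genes, and 0 of 16 were called higher by edgeR (1194 of all genes had an unadjusted p under 0.05, and 190 of all genes were higher by DESeq2). That outcome decides little, because only 75 of all 30384 genes were called higher here. The 16 also include L and S copies of the same gene, and several had no counts in some libraries. No further biological explanation was tested.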

How the results depend on the processing

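Thinning every library to the smallest total and the replicate block within each time were chosen after the data were seen, and the other alternatives were planned. Over all alternatives 3373 results of named genes kept their side of the threshold, 901 lost the call, 3 gained it and 5 reversed direction. For results called in neither fit a change of direction was not counted. Of the 275 called ones 72 kept the call in every alternative. Of list tests 1150 kept their side, 123 lost and 27 gained the call. Counts stayed within 1.5 times in 167 cases and moved further in 259. The 5 reversals came with L and S copies summed, where the copies themselves differ: krt19.S -0.35 and cdh1.L -0.46 with Ptf1a at 25 h, krt19.S -0.03 with the mutant at 25 h, and angptl4.S -0.06 and neurog2.S 6.88 with Neurog2 at 6 h. Fits of fewer libraries have fewer residual degrees of freedom, and for the other changes the cause was not tested. Thinning shows what depth limits: 36 of 274 called results of named genes lost the call. DESeq2 size factors changed the share of called genes that were higher with Ptf1a at 25 h from 57.9 to 48.3%.

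Counts below are of higher and lower genes, as in 416 and 17, and a single count has its direction given. With the replicate block they moved to 416 and 17 for Ptf1a at 6 h, 131 lower for Neurog2 at 25 h, 288 and 3 for the mutant at 6 h and 367 and 42 at 25 h. Ptf1a against the mutant gave 19 higher at 6 h and 2280 and 2168 at 25 h, Ptf1a against Neurog2 70 higher and 2578 and 2166, and the mutant against Neurog2 9 and 4 higher. Effects differing between the times numbered 2046 and 2643 for Ptf1a, 95 and 48 for Neurog2 and 36 and 96 for the mutant. With the block within each time, comparisons with the control gave 686 and 55 for Ptf1a at 6 h, 5875 and 4994 at 25 h, 149 and 7 for Neurog2 at 6 h, 1716 and 441 at 25 h, 525 and 8 for the mutant at 6 h and 586 and 193 at 25 h. Ptf1a against the mutant gave 57 and 7, then 3579 and 3696, Ptf1a against Neurog2 154 and 20, then 3868 and 3635, and the mutant against Neurog2 35 and 4, then 20 and 13. Differences between the times were 3048 and 4184, 206 and 141, and 99 and 253.

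The DESeq2 Wald test gave 481 and 90 for Ptf1a at 6 h, 4310 lower at 25 h, 190 and 7 for Neurog2 at 6 h, 1511 and 322 at 25 h, 460 and 11 for the mutant at 6 h and 749 and 201 at 25 h. Ptf1a against the mutant gave 72 and 6, then 2254 and 2702, Ptf1a against Neurog2 121 and 25, then 2377 and 2607, and the mutant against Neurog2 51 and 10, then 32 and 93. Differences between the times were 2411 and 2619, 609 and 181, and 257 and 237. DESeq2 size factors moved Neurog2 at 25 h to 61 lower, Ptf1a against the mutant at 6 h to 0 lower (500 at an unadjusted p under 0.05 in edgeR) and the mutant against Neurog2 at 6 h to 1 higher. Without a filter on low counts Ptf1a against the mutant gave 19 and against Neurog2 61 higher at 6 h, the mutant against Neurog2 9 higher, and the mutant 66 effects lower at 25 h than at 6 h. Summed copies gave 1 lower for Ptf1a at 6 h, 45 and 0 for Neurog2 at 6 h, 0 lower for the mutant at 6 h and 6 higher for the mutant against Neurog2 at 6 h. Thinned libraries gave 8 lower for Ptf1a and 0 lower for Neurog2 at 6 h, and for the mutant against Neurog2 1 and 1 at 6 h and 1 higher at 25 h. A minimum change of 2-fold left 19 of the 29 genes lower with both Ptf1a and Neurog2 at 25 h.

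A fit of the 8 libraries of a time gave 97 higher for Ptf1a at 6 h, 24 and 0 for Neurog2 at 6 h, 240 and 0 at 25 h, 66 and 0 for the mutant at 6 h and 7 and 0 at 25 h. Ptf1a gave 0 and 0 against the mutant and 3 and 1 against Neurog2 at 6 h, and the mutant against Neurog2 1 and 1, then 0 and 0. A fit of the 4 libraries compared gave 7 and 0 for Ptf1a at 6 h, 2 and 0 for Neurog2 at 6 h, 0 and 0 at 25 h, 12 and 0 for the mutant at 6 h and 0 and 0 at 25 h. Ptf1a against the mutant gave 0 and 0, then 665 and 412, Ptf1a against Neurog2 0 and 1, then 799 and 828, and the mutant against Neurog2 0 and 1, then 0 and 0. These zeros are of edgeR, and the DESeq2 counts stand above. With all 16 libraries, genes at an unadjusted p under 0.05 numbered 2137 for Ptf1a, 1194 for Neurog2 and 1981 for the mutant at 6 h and 3685 for Neurog2 and 2751 for the mutant at 25 h. They numbered 500 for Ptf1a against the mutant and 843 against Neurog2 at 6 h, and 716 and 1303 for the mutant against Neurog2 at 6 h and 25 h. These numbers, and the 1194 for Neurog2 at 6 h, lie below a share of 0.05 of the 30384 genes tested. They give no sign of further changed genes in this fit, and they cannot exclude such genes. The fit does not use the pairing of replicates, and the blocked fits and DESeq2 called more genes in these comparisons, as given above.

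With single libraries left out the higher counts ranged from 84 to 213 for Ptf1a at 6 h and 1689 to 2772 at 25 h, and the lower ones from 1 to 3 and 1270 to 1874. For Neurog2 they were 16 to 50 and 11 to 1320 higher and 0 to 0 and 0 to 99 lower, and for the mutant 52 to 387 and 1 to 436 higher and 0 to 1 and 0 to 46 lower. Ptf1a against the mutant gave 4 to 12 and 235 to 971 higher and 0 to 0 and 158 to 871 lower, against Neurog2 7 to 37 and 554 to 1072 higher and 2 to 2 and 458 to 798 lower. The mutant against Neurog2 gave 1 to 7 and 0 to 3 higher and 1 to 1 and 1 to 57 lower. The controls gave 7375 to 7795 higher and 7551 to 8153 lower. Differences between the times were 570 to 1072 and 734 to 1463 for Ptf1a, 0 to 468 and 0 to 48 for Neurog2 and 2 to 56 and 9 to 97 for the mutant.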

Other observations

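The comparison of L and S copies and the pairs named for it were chosen after the results were seen, while the list tests were planned.

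Many genes exist as an L and an S copy, and the copies did not always move together. Of 7996 pairs, 892 had both copies called in the same direction with Ptf1a at 25 h, 39 in opposite directions and 2055 only 1 copy called, and over 6005 pairs with enough counts the changes correlated at 0.70. Between the controls of 25 h and 6 h these counts were 2876, 560 and 3178. Opposite pairs with Ptf1a were clmp (5.17 for L, -2.92 for S), efnb2 (-1.74, 2.88) and ttll7 (-1.66, 4.40). Of the keratin gene krt19, the L copy stood at 1500 and 2310 CPM in the Ptf1a caps against 3260 and 2860 in the controls, and the S copy at 426 and 604 against 69.4 and 80.6 CPM.

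Anterior-posterior patterning genes rose in 9 of 56 cases and fell in 9 with Ptf1a at 25 h (10 and 11 adjusted over the list alone), without passing camera (adjusted p = 0.148), and had a median of -1.07 with bounds with the mutant (0 called; adjusted p = 2.34e-08, and adjusted p = 0.0675 with an estimated correlation). Early ectoderm genes fell in 12 of 45 cases and rose in 2 with Ptf1a (18 and 3 alone; adjusted p = 4.58e-05, and adjusted p = 0.261 with an estimated correlation), and glia genes rose in 5 of 14 and fell in 1 (6 and 1 alone; adjusted p = 0.0166, and adjusted p = 0.238 with an estimated correlation). With Neurog2 at 25 h 3 of 17 motor and cholinergic members rose (3 alone), both copies of olig2 and slc18a3.L. As a list they passed camera at adjusted p = 0.00382, and gave adjusted p = 0.234 with an estimated correlation. The vesicular acetylcholine transporter gene slc18a3.L was at least 104-fold higher. With Ptf1a at 25 h pancreas genes rose in 7 of 32 cases and fell in 6 (8 and 6 alone; adjusted p = 0.754), retina genes rose in 4 of 31 (2 alone; adjusted p = 0.485), and mesoderm and muscle genes rose in 13 of 45 and fell in 2 (14 and 2 alone; adjusted p = 0.177). Endoderm genes rose in 2 of 19 and fell in 2 (2 and 2 alone; adjusted p = 0.402), p53 and stress genes rose in 4 of 43 and fell in 6 (4 and 6 alone; adjusted p = 0.113), and glucocorticoid response genes rose in 5 of 24 and fell in 2 (5 and 3 alone; adjusted p = 0.876).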
